A study of Mus musculus with 17 samples.

How the data were processed

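Polyadenylated RNA from the frontal cortex of 17 male C57BL/6J offspring was sequenced as single-end reads of 100 bp from strand-specific libraries, per the labels' protocols. Brains were sliced coronally and the dissection was meant to keep out olfactory and putamen tissue, per the same protocols. The authors deposited 1 table of TPM values per gene, rounded to 2 decimals and scaled so that each of the 17 columns sums to the same total. Trim Galore 0.4.0, STAR 2.5.1b, RSEM 1.2.31 and the mouse build mm10 are named in the submitters' processing notes. RSEM assigns reads that match several transcripts by expectation maximization, so a gene with near-identical copies receives an estimated share of the reads. The annotation release, the strand setting of the counting and any filter are not given in the sources used here.

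The labels state 25 M reads (reads in units of 1e+06) for the sequencing. TPM keeps no library depth, so no count test, interval of counts or detection floor was computed. TPM is also relative, so a shift in a few abundant transcripts moves all other values, and values were therefore tested under other scalings. Each column was tied to its sample by its name, which matches the sample's description, and groups were taken from the labels. Of 48440 gene identifiers, 48058 matched a symbol when the version suffix was left off and 40606 matched with it. Coordinates and gene types came from GENCODE release M21 on GRCm38, the assembly that mm10 also names, which may not be the annotation behind the table. No 2 libraries held identical values, and Pearson's r between libraries across genes ran from 0.987 to 0.993, where genes are not independent replicates.

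Genes with a TPM of at least 1 in at least 8 libraries were kept, which left 14144. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(TPM + 1), two-sided, with Benjamini-Hochberg adjustment. A fold change on this scale understates the change of genes with low TPM. The procedure was tested on simulated data with 14144 genes, 20 simulations and 50 genes changed at each fold, drawn independently between genes, and 4.29% of its calls were false. It called 48.5% of 1.2-fold, 88.5% of 1.5-fold, 96.8% of 2-fold and 98.3% of 3-fold changes. These shares hold for that many changed genes, since the adjustment is stricter where fewer genes change.

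A total of 41 gene lists covering immune signalling, brain cell types, neighbouring tissues, neurotransmission, stress, metabolism and disease association was fixed before the data were examined, together with the design, the rule for named genes and most alternatives. For each list the mean log2(TPM + 1) of its measured members was compared between the groups by a two-sided exact permutation test over all 24310 splits of the 17 libraries, with Benjamini-Hochberg adjustment over the 40 lists that had at least 5 measured members. Intervals of 95% were found by inverting the same test. Choroid plexus and ependyma, with 4 measured members, was described only, and the sex-linked genes served as a check of the labels. Principal components 1 to 5 of the tested genes were compared by exact permutation. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

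The genes named are the 12 with the smallest p in each direction, at most 3 unnamed models, the members of each list with the smallest p and, for cell type lists, the most abundant. The rule allowed up to 3 members by p and 2 by abundance, of which 2 and 1 were used, and 2 list members that it names are not reported here. Drd2, Adora2a, Syndig1l, Cdhr1, Doc2g and Th, given for libraries that stood apart, were chosen after their values were seen. Near-identical copies of the leading genes and of mitochondrial transcripts were searched among the M21 transcripts with BLAST 2.17.0 at a minimum identity of 97%.

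The alternatives were pseudocounts of 0.1 and 0.5, no filter and a minimum TPM of 5, median-of-ratios, upper-quartile and quantile scaling, robust eBayes, array weights, the rank test, an adjusted p of 0.1, the replicate number as a block, the first principal component, the myelin list or the striatal list as a covariate, and leaving out each library in turn. For lists they also included mean z scores, camera with a preset correlation of 0.01 or an estimated correlation, and fry. For components they were unit variance scaling and the 500 most variable genes. Leaving out Poly(I:C) replicate 7 with saline replicate 7, and rescaling without mitochondrial genes and their copies or without the 50 most abundant genes, were chosen after seeing the data. Behaviour was not analysed here.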

Results

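Frontal cortex was profiled by RNA sequencing in 17 male C57BL/6J mice at postnatal day 189. Of these offspring, 9 came from dams injected intraperitoneally with Poly(I:C) at 20 mg/kg at G12.5 (gestational day), and 8 came from dams given saline. Poly(I:C) is a synthetic double-stranded RNA that engages antiviral innate immune receptors, and its injection during pregnancy is used to model maternal immune activation. The comparison asked which transcripts of the adult frontal cortex differed between the 2 prenatal groups. Abundance was given as TPM for 48440 genes, of which 14144 reached a TPM of at least 1 in at least 8 libraries and were tested. The depth of each library is unknown, since TPM values sum to the same total in every library.

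The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, which are carried by males only, were present in all 17 libraries. Ddx3y stood at 14.4 ± 0.746 TPM in the Poly(I:C) group (SD, n = 9) and 15.0 ± 1.54 TPM in the saline group (SD, n = 8). Xist, the transcript of the inactive X chromosome, reached at most 0.15 TPM in any library. Uty was measured at 4.45 and 4.50 TPM, Kdm5d at 7.03 and 7.25 TPM, and Eif2s3y at 30.6 and 35.2 TPM in the Poly(I:C) and saline groups, with log2 differences of -0.014, -0.042 and -0.20 as deposited. None of the 4 passed the limma test over all genes, the adjusted p of Eif2s3y being 0.535. The small differences of Uty, Kdm5d and Ddx3y changed sign under another scaling, sample set or covariate. Genes with a TPM above 0 numbered 20374 ± 242 in the Poly(I:C) libraries (SD, n = 9) and 20699 ± 201 in the saline libraries (SD, n = 8). The exact permutation p of this count was 0.0112 and its adjusted p over 5 library measures 0.0559. Mitochondrial genes and their near-identical nuclear copies took 40.0% ± 1.52 of the TPM in the Poly(I:C) libraries (SD, n = 9) and 39.0% ± 1.64 in the saline libraries (SD, n = 8), with an exact permutation p of 0.179.

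No gene passed an adjusted p of 0.05 between the adult offspring of Poly(I:C) and saline dams. The ribosomal protein retrogene Rps27rt had the smallest p, at 56.5 ± 8.18 TPM in the Poly(I:C) group (SD, n = 9) and 38.9 ± 6.44 TPM in the saline group (SD, n = 8). Naa10, the catalytic subunit of an N-terminal acetyltransferase, stood at 33.6 ± 1.63 TPM (SD, n = 9) against 38.2 ± 1.196 TPM (SD, n = 8). Polr2a, the largest subunit of RNA polymerase II, stood at 29.1 ± 1.41 TPM (SD, n = 9) against 33.9 ± 2.37 TPM (SD, n = 8). The mitochondrial transcript mt-Co2, which encodes a subunit of cytochrome c oxidase, was measured at 1145 ± 156 TPM (SD, n = 9) and 857 ± 133 TPM (SD, n = 8). It held 2.41% of the TPM summed with its near-identical nuclear copy Gm28661. The gene models 1110008P14Rik, at 358 and 322 TPM, and Gm21093, at 27.02 and 22.02 TPM, shared the smallest adjusted p of 0.140 with Rps27rt and Naa10.

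On the log2(TPM + 1) scale, the difference between the groups was 0.53 ± 0.093 (SE) for Rps27rt, 0.15 ± 0.029 for 1110008P14Rik, 0.28 ± 0.054 for Gm21093 and -0.18 ± 0.034 for Naa10. Rps27rt, 1110008P14Rik and Gm21093 lay above the saline median in 9 of 9 Poly(I:C) libraries, and Naa10, Polr2a and Gm8325 in 0 of 9. Other leading genes with values higher in the Poly(I:C) group, none of which passed, were mt-Co2 (0.42 ± 0.090), the antisense transcript Ccdc142os (0.37), the neuropeptide precursor Cartpt (0.44), the transcription factor Ascl5 (0.37) and the mitochondrial inner membrane protein gene Apool (0.24). They were followed by the retinoid receptor Rxra (0.23), the membrane protein gene Smim1 (0.19), the histone gene Hist1h2bc (0.17), beta-actin (Actb, 0.16), the signalling scaffold Git1 (0.11) and the ribosomal protein gene Rpl29 (0.095). Leading genes with lower values were Polr2a (-0.21 ± 0.042), LTO1 (-0.35), Ggnbp1 (-0.37), the histone methyltransferase subunit Ash2l (-0.17), Tceal5 (-0.27) and the RNA polymerase I initiation factor Taf1b (-0.18). The core-binding factor subunit Cbfb (-0.22), the metalloproteinase Mmp16 (-0.30), the poly(ADP-ribose) hydrolase Parg (-0.27), the zinc finger gene Zfp326 (-0.28), the cytokine Flt3l (-0.23) and the pseudogene Gm8325 (-0.36) completed this set. All 27 of these genes were named by smallest p, and their adjusted p ran from 0.140 to 0.486.

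**Figure D1:**
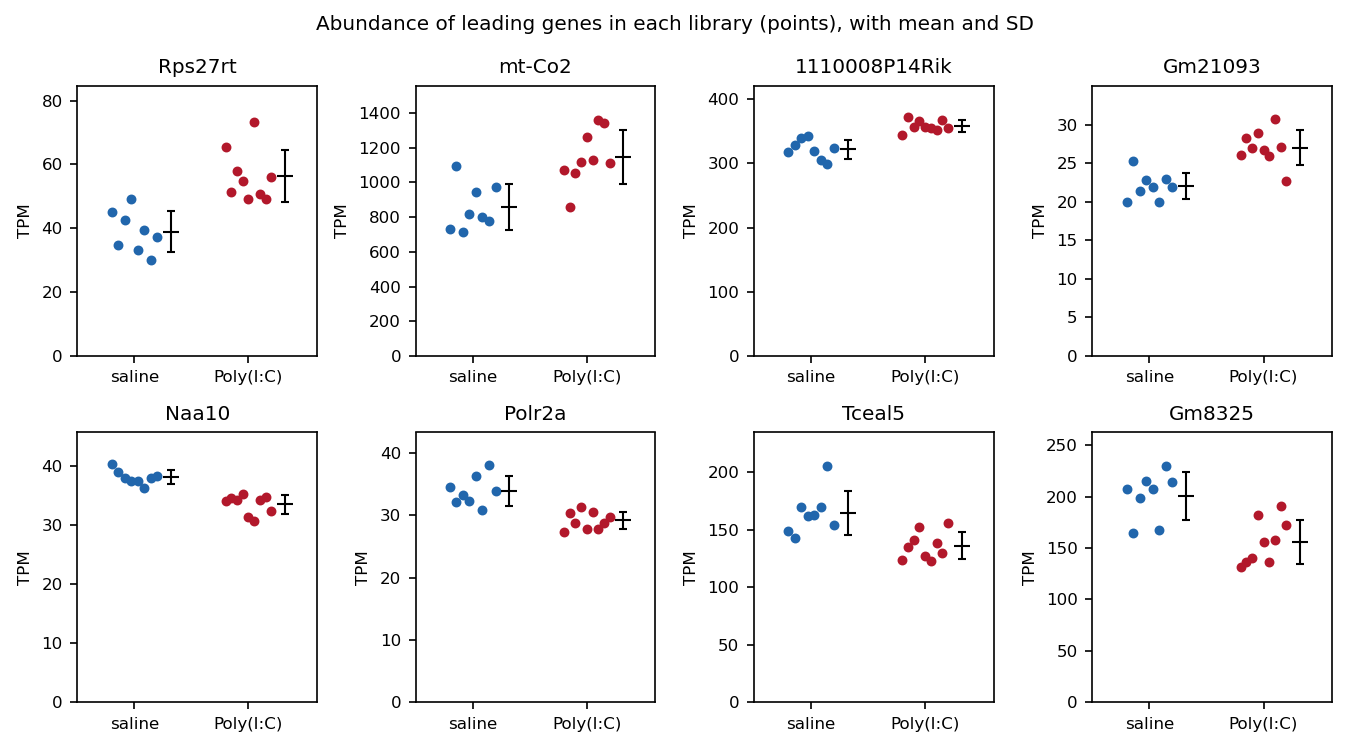
TPM of 8 leading genes in each library, with saline libraries in blue and Poly(I:C) libraries in red; each point is 1 library, and the black marks give the mean and SD of 8 saline and 9 Poly(I:C) libraries. Rps27rt averages 56.5 TPM in the Poly(I:C) group against 38.9 TPM in the saline group and Naa10 33.6 against 38.2 TPM, and no gene shown passed an adjusted p of 0.05 in limma.

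On the mouse assembly GRCm38, Rps27rt (ENSMUSG00000050621.6) lies on chromosome 9 from 114982366 to 114982739, and Naa10 (ENSMUSG00000031388.14) on chromosome X from 73916873 to 73921944. 1110008P14Rik (ENSMUSG00000039195.4) occupies chromosome 2 from 32377097 to 32381938, Gm21093 (ENSMUSG00000096256.1) chromosome 4 from 42033017 to 42034726, and mt-Co2 (ENSMUSG00000064354.1) positions 7013 to 7696 of the mitochondrial genome. All 5 are annotated as protein-coding, whereas Gm8325, on chromosome 3 from 60877014 to 60877587, is annotated as a transcribed processed pseudogene. Rps27rt shares 341 of its 374 bases with Rps27 at 100% identity, mt-Co2 shares 681 of 684 bases with Gm28661 on chromosome 1 at 100%, and Gm8325 shares 424 of 453 bases with Ube2v1 at 99.5%. Gm21093 has 8 near-identical copies above 1 TPM on chromosome 4, among them Gm3883 at 100% identity over 1710 bases. Of the 27 leading genes 7, among them Rps27rt, Naa10, 1110008P14Rik and Ccdc142os, overlap another annotated gene with a mean of at least 1 TPM, Naa10 overlapping Arhgap4 on its own strand and the others on the opposite strand.

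By limma with Benjamini-Hochberg adjustment 0 of 14144 genes passed an adjusted p of 0.05, with 1237 genes under an unadjusted p of 0.05 where evenly spread p-values would give 707.2. The Mann-Whitney test per gene also gave 0 genes, with 1132 under an unadjusted p of 0.05. Of the 1237 genes, 127 were higher and 1110 lower in the Poly(I:C) group as deposited. After median-of-ratios scaling 1038 genes lay under an unadjusted p of 0.05, of which 548 were higher and 490 lower. Over all tested genes 71.0% were lower as deposited, with a median log2 difference of -0.035, and 50.9% after median-of-ratios scaling. That scaling levels the median gene ratio between libraries, so a nearly even share follows from it by construction. Median-of-ratios scaling brought 2 genes, 1110008P14Rik and Gm21093, past the threshold at an adjusted p of 0.0492, and without saline replicate 4 Rps27rt passed at 0.0442. An absolute log2 difference of at least 0.5 was seen in 44 genes and of at least 1 in 5 genes. The median SE of a log2 difference was 0.061. In simulated data of this size with 50 genes changed at each fold, 48.5% of genes changed 1.2-fold and 88.5% of genes changed 1.5-fold were called. The adjustment is stricter where fewer genes change, so these shares overstate the power to find a few changed genes. The labels mention 11 dams without tying the 17 offspring to litters, so the p-values treat littermates as independent animals.

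No list of innate immune transcripts passed between the groups. Measured members were 23 of 34 interferon and 26 of 37 cytokine genes. They were 20 of 26 for NF-kB and Toll-like receptor genes and 20 of 27 for complement and class I genes. The remaining members were not tested. The 23 measured interferon response genes, which antiviral signalling induces, differed by -0.016 on the log2 scale as deposited, with a 95% interval of -0.077 to 0.041, and by 0.011 after median-of-ratios scaling. Their leading members were Ifit3, at 7.08 and 7.68 TPM in the Poly(I:C) and saline groups, and the RNA sensor gene Ddx58, at 1.93 and 2.20 TPM. Cytokine and chemokine signalling genes had the smallest p of all lists, with a difference of -0.048 (95% interval -0.088 to -0.0086), 19 of 26 members lower and an exact permutation p of 0.0211 that became 0.437 after adjustment over 40 lists. In that list the chemokine Cxcl12 stood at 20.4 ± 1.80 TPM (SD, n = 9) against 23.3 ± 1.99 TPM (SD, n = 8). The tumour necrosis factor receptor Tnfrsf1a stood at 7.48 ± 1.09 TPM (SD, n = 9) against 9.14 ± 1.25 TPM (SD, n = 8). The list remained lower at -0.017 after median-of-ratios scaling. Its 19 of 26 lower members as deposited stand beside 71.0% lower over all tested genes. Genes of the NF-kB and Toll-like receptor pathways differed by -0.030 as deposited and 0.0020 after that scaling, with Tnfaip3 at 2.06 and 2.45 TPM and Ikbkg at 15.2 and 17.7 TPM. Complement and major histocompatibility class I genes differed by -0.022 and 0.0088 in the same order, with the antigen-processing genes Tapbp at 12.8 and 11.5 TPM and Tap1 at 1.09 and 0.949 TPM. No member of these 4 lists passed over all genes tested, and 0 passed adjusted over the list alone.

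No glial or vascular list passed between the groups. The microglial list differed by -0.012 in its mean (95% interval -0.066 to 0.043) and 0.0030 in the median of its members, with 12 of 24 members higher, and its mean difference was 0.023 after median-of-ratios scaling and 0.0018 without Poly(I:C) replicate 7 and saline replicate 7. Within it Slc2a5, a sugar transporter of microglia, stood at 3.71 ± 0.676 TPM (SD, n = 9) against 4.75 ± 0.541 TPM (SD, n = 8). Slc2a5 was the 1 member to pass adjusted over the list alone in limma (adjusted p = 0.0488), and the protease gene Ctss stood at 64.6 and 68.9 TPM. Astrocyte genes differed by -0.0020 as deposited, 0.034 after median-of-ratios scaling and -0.022 without these 2 libraries, with glutamine synthetase (Glul) at 1550.2 and 1450.2 TPM and S100b at 108 and 103 TPM. Oligodendrocyte and myelin genes differed by 0.047 (95% interval -0.13 to 0.23), with myelin basic protein (Mbp) at 1278 and 1155 TPM, Cryab at 104 and 93.0 TPM and Ermn at 14.5 and 13.1 TPM. Their difference was 0.082 after median-of-ratios scaling and -0.012 without these 2 libraries. Oligodendrocyte precursor genes differed by -0.029 (Pdgfra 10.9 and 11.7 TPM, Xylt1 10.8 and 11.7 TPM). Their most abundant member, Bcas1, stood at 88.3 and 82.1 TPM, a difference of 0.083 that was -0.0014 without these 2 libraries. Endothelial genes differed by -0.021 (Adgrl4 19.5 and 16.6 TPM, Egfl7 34.7 and 37.0 TPM) and pericyte and smooth muscle genes by -0.029 (Abcc9 1.99 and 2.21 TPM, Pdgfrb 6.17 and 6.60 TPM, Vtn 42.6 and 45.1 TPM). Bsg, the most abundant member of the endothelial list at 350.2 and 353 TPM, differed by -0.012 as deposited and 0.026 after median-of-ratios scaling. After median-of-ratios scaling the differences of these 3 lists were 0.0028, 0.013 and -0.00034, and the pericyte list turned to 0.0089 with quantile normalization. Meningeal fibroblast genes differed by -0.097, with all 19 members lower as deposited, among them Slc6a13 at 3.98 and 4.75 TPM, Nnat at 72.3 and 81.7 TPM and the prostaglandin synthase Ptgds at 1181 and 1293 TPM. After that scaling the difference was -0.065, and its adjusted p as deposited was 0.590 by exact permutation. Blood cell genes differed by 0.024, or 0.053 after median-of-ratios scaling and -0.062 with a pseudocount of 0.1, with Hbb-bt at 17.4 and 14.6 TPM. The 4 measured choroid plexus and ependymal genes, too few to test, differed by -0.051 and included Rarres2 at 3.36 and 4.14 TPM and Foxj1 at 2.03 and 1.86 TPM. Enpp2, their most abundant member at 98.7 and 100.1 TPM, differed by -0.020 as deposited and 0.017 after median-of-ratios scaling.

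In striatal and olfactory bulb markers, single libraries stood apart. Poly(I:C) replicate 7 had the highest striatal list mean, 4.21 on the log2 scale where the other Poly(I:C) libraries lay between 3.48 and 3.84, with the dopamine receptor Drd2 at 7.57 TPM against a median of 1.27 TPM in the other 16 libraries and the adenosine receptor Adora2a at 5.41 against 1.19 TPM. Its myelin list mean was 5.48, with the other Poly(I:C) libraries between 4.64 and 5.03. Saline replicate 7 had the highest olfactory list mean, 3.98 where the other saline libraries lay between 3.15 and 3.33, with the photoreceptor cadherin Cdhr1 at 11.0 TPM against a median of 1.01 TPM and Doc2g at 21.8 against 2.46 TPM. Between the groups the striatal list differed by 0.099 (95% interval -0.055 to 0.28), with 18 of 20 members higher, by 0.13 after median-of-ratios scaling and by 0.045 without these 2 libraries. The olfactory list differed by -0.12 (95% interval -0.31 to 0.010), with 19 of 20 members lower, by -0.093 after that scaling and by -0.035 without them. Neither list passed, with adjusted p of 0.734 and 0.577 by exact permutation, and their leading members were Rasd2 (50.7 and 45.7 TPM), Ppp1r1b (92.0 and 80.1 TPM), Etv1 (51.1 and 60.3 TPM), Pax6 (11.6 and 13.1 TPM) and Meis2 (157 and 173 TPM). Without the 2 libraries 0 genes passed in limma and 819 lay under an unadjusted p of 0.05.

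**Figure D2:**
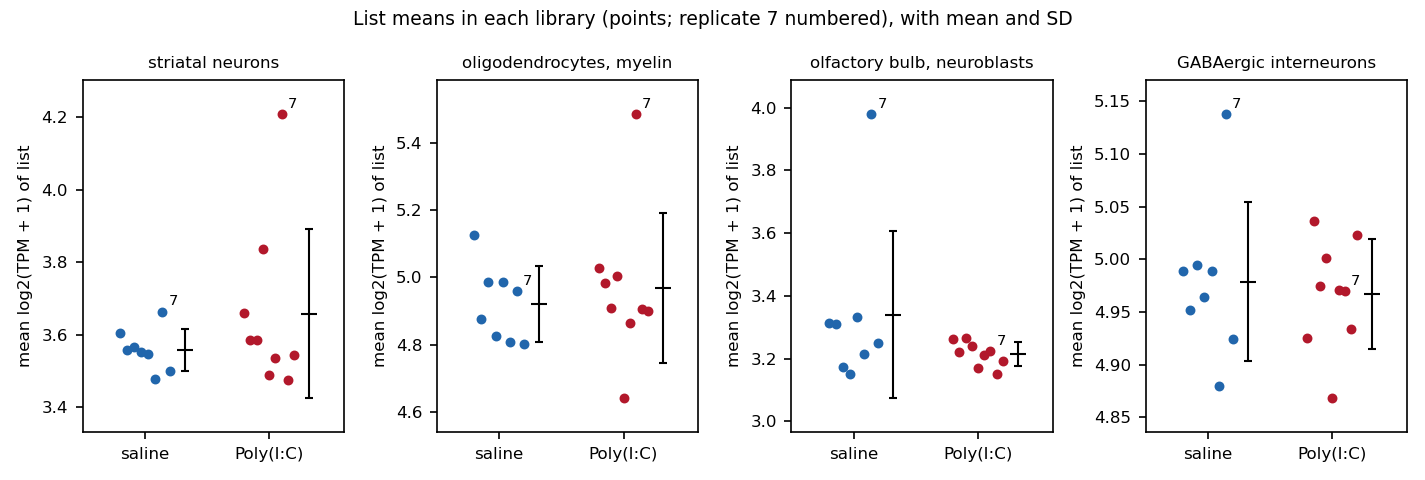
Mean log2(TPM + 1) over the members of 4 marker lists in each library, with saline libraries in blue and Poly(I:C) libraries in red; each point is 1 library, replicate 7 of each group is numbered, and black marks give the mean and SD of 8 saline and 9 Poly(I:C) libraries. Poly(I:C) replicate 7 lies at 4.21 in striatal markers and 5.48 in myelin markers, and saline replicate 7 at 3.98 in olfactory markers and 5.14 in interneuron markers.

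Apart from the striatal and olfactory lists, the most negative differences among neuronal lists were those of immediate early genes and glutamate receptors, and neither passed. The 24 glutamate receptor genes differed by -0.074 (95% interval -0.15 to 0.0011), with 21 members lower as deposited, an exact permutation p of 0.0531 and an adjusted p of 0.437, and the difference was -0.039 after median-of-ratios scaling. Poly(I:C) replicate 7 had the lowest value of this list, 4.58, and saline replicate 7 the highest, 4.88, and without them the difference was -0.045 with an exact permutation p of 0.187. Grm7, a presynaptic metabotropic receptor, stood at 21.1 ± 1.95 TPM (SD, n = 9) against 24.1 ± 1.90 TPM (SD, n = 8). The AMPA receptor subunit Gria2 stood at 205 ± 11.4 TPM (SD, n = 9) against 228 ± 18.6 TPM (SD, n = 8). Grm7 and Gria2 were the 2 members to pass adjusted over the list alone in limma (adjusted p = 0.0483 for both). Immediate early genes, which neuronal activity induces, differed by -0.13 (95% interval -0.33 to 0.071), with 24 of 30 members lower as deposited and the activity-dependent factor Npas4 at 9.34 ± 3.22 TPM (SD, n = 9) against 14.03 ± 4.90 TPM (SD, n = 8) and Jun at 17.7 and 20.1 TPM. That list differed by -0.092 after median-of-ratios scaling. Over all tested genes 71.0% were lower as deposited. Upper layer excitatory genes differed by -0.029 (Otof 6.06 and 7.33 TPM, Lamp5 274 and 257 TPM), deep layer excitatory genes by -0.021 (Crym 24.2 and 31.5 TPM, Pcp4 454 and 428 TPM). Interneuron genes differed by -0.012 (Adarb2 4.91 and 5.62 TPM, Npy 555 and 516 TPM, Cck 871 and 861 TPM). GABA receptor genes differed by -0.028 (Gabra5 39.2 and 42.9 TPM, Gabbr1 415 and 426 TPM), monoamine and acetylcholine receptor genes by -0.016 (Chrnb2 13.5 and 14.4 TPM, Htr2c 4.49 and 5.15 TPM). Presynaptic release genes differed by -0.0018 (Cplx2 567 and 541 TPM, Syp 819 and 857 TPM), postsynaptic scaffold genes by -0.028 (Cacng8 32.7 and 35.4 TPM) and voltage-gated channel genes by -0.016 (Cacna1h 16.7 and 20.2 TPM, Scn3a 6.69 and 7.50 TPM). All 8 of these last lists were above 0 after median-of-ratios scaling, between 0.0061 and 0.035, and saline replicate 7 had the highest interneuron list mean. Without replicate 7 of both groups, the differences were -0.014 for upper layer, -0.0052 for deep layer and 0.011 for interneuron genes. They were -0.0017 for GABA receptors, -0.0036 for monoamine and acetylcholine receptors, 0.0060 for presynaptic, -0.010 for postsynaptic and -0.00073 for channel genes in the same libraries.

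Of the other signalling lists, Wnt pathway genes and perineuronal net genes had an unadjusted p under 0.05. Wnt pathway genes differed by -0.053 (95% interval -0.098 to -0.0074), with 26 of 34 members lower as deposited, an exact permutation p of 0.0273 and an adjusted p of 0.437, led by Dvl2 at 13.6 and 15.7 TPM and the receptor Fzd8 at 1.14 and 1.36 TPM. Perineuronal net and matrix genes differed by -0.036 (95% interval -0.071 to -0.00076) with an exact permutation p of 0.0462 and an adjusted p of 0.437. In this list Mmp16, at 8.82 ± 1.11 TPM (SD, n = 9) against 11.1 ± 1.31 TPM (SD, n = 8), was the 1 member to pass adjusted over the list alone in limma (adjusted p = 0.00954), and Mmp14 stood at 5.37 and 6.13 TPM. After median-of-ratios scaling the Wnt list differed by -0.021 and the perineuronal net list by -0.0019, and the latter reached 4.4e-05 with quantile normalization. The 26 of 34 lower members of the Wnt list as deposited stand beside 71.0% lower over all tested genes. Growth factor genes differed by -0.025 (Fgf1 26.2 and 24.8 TPM, Igf2 29.3 and 32.5 TPM), mTOR and translation control genes by -0.043 (Rictor 7.27 and 8.25 TPM, Rps6kb2 28.0 and 31.2 TPM). Chromatin regulators differed by -0.053 (Chd3 207 and 222 TPM, Chd8 21.8 and 23.4 TPM). Autism-associated genes differed by -0.048, with the transcription factors Adnp at 6.98 ± 1.37 TPM (SD, n = 9) against 9.53 ± 2.43 TPM (SD, n = 8) and Mef2c at 317 and 359 TPM. Schizophrenia-associated genes differed by -0.024, with Setd1a at 20.3 and 22.5 TPM. The growth factor and schizophrenia lists turned to 0.0095 and 0.011 after median-of-ratios scaling, and the mTOR, chromatin and autism lists stayed lower at -0.0078, -0.018 and -0.013. Saline replicate 7 had the highest autism list mean of the 17 libraries, 5.296, and without Poly(I:C) replicate 7 and saline replicate 7 the autism list differed by -0.022 (exact permutation p of 0.486) and the schizophrenia list by -0.012.

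Among metabolic and stress lists the mitochondrially encoded genes had the most positive difference, 0.094 (95% interval -0.0023 to 0.19), with 12 of 15 members higher, an exact permutation p of 0.0546 and an adjusted p of 0.437. It was 0.13 after median-of-ratios scaling, and the median difference of its members as deposited was 0.045. In this list mt-Co2 passed adjusted over the list alone in limma (adjusted p = 0.00242) and mt-Atp6 stood at 2622 and 2193 TPM. Of the TPM summed with its copy Gm28661, mt-Co2 held 2.41%. That sum was 42289 TPM in the Poly(I:C) group and 41524 TPM in the saline group, with an exact permutation p of 0.403. Mitochondrial transcripts had 8 near-identical nuclear copies in the table, of which Gm10925 averaged 51015 TPM. Within this list only mt-Co2 was summed with a copy, so shared reads stay open for mt-Atp6 and the other members. The nuclear genes of oxidative phosphorylation differed by -0.016 (Ndufa1 150.2 and 169 TPM, Ndufv1 106 and 114 TPM) and cytosolic ribosomal protein genes by -0.025 (Rpl30 166 and 184 TPM, Rps29 456 and 505 TPM). These turned to 0.021 and 0.012 after median-of-ratios scaling. Cholesterol synthesis genes differed by -0.076, or -0.040 after that scaling, with lanosterol synthase (Lss) at 16.3 and 19.8 TPM and Fdft1 at 51.8 and 56.1 TPM. Heat shock genes differed by -0.025, or 0.011 after that scaling, with the mitochondrial chaperonin Hspd1 at 87.2 ± 8.90 TPM (SD, n = 9) against 100.3 ± 7.32 TPM (SD, n = 8). Hspd1 was the 1 member to pass adjusted over the list alone in limma (adjusted p = 0.0346), and Hsp90aa1 stood at 592 and 659 TPM. Unfolded protein response genes differed by 0.0091 (Canx 125 and 135 TPM, Eif2ak3 12.3 and 13.5 TPM), glucocorticoid-responsive genes by 0.014, or -0.012 without Poly(I:C) replicate 7 and saline replicate 7 (Mt1 537 and 502 TPM, Arl4d 14.4 and 15.8 TPM). Circadian clock genes differed by -0.0048 (Rora 14.4 and 12.99 TPM, Rorb 5.78 and 5.31 TPM) and oxidative stress genes by 0.0052 in the mean and -0.014 in the median (Gpx1 158 and 148 TPM, Sod1 255 and 270.5 TPM). After median-of-ratios scaling the circadian list turned to 0.031, and the unfolded protein, glucocorticoid and oxidative stress lists differed by 0.045, 0.049 and 0.041. Without Poly(I:C) replicate 7 and saline replicate 7 the differences were -0.0064 for nuclear oxidative phosphorylation, -0.0076 for heat shock, 0.017 for unfolded protein response and -0.010 for circadian clock genes.

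**Figure D3:**
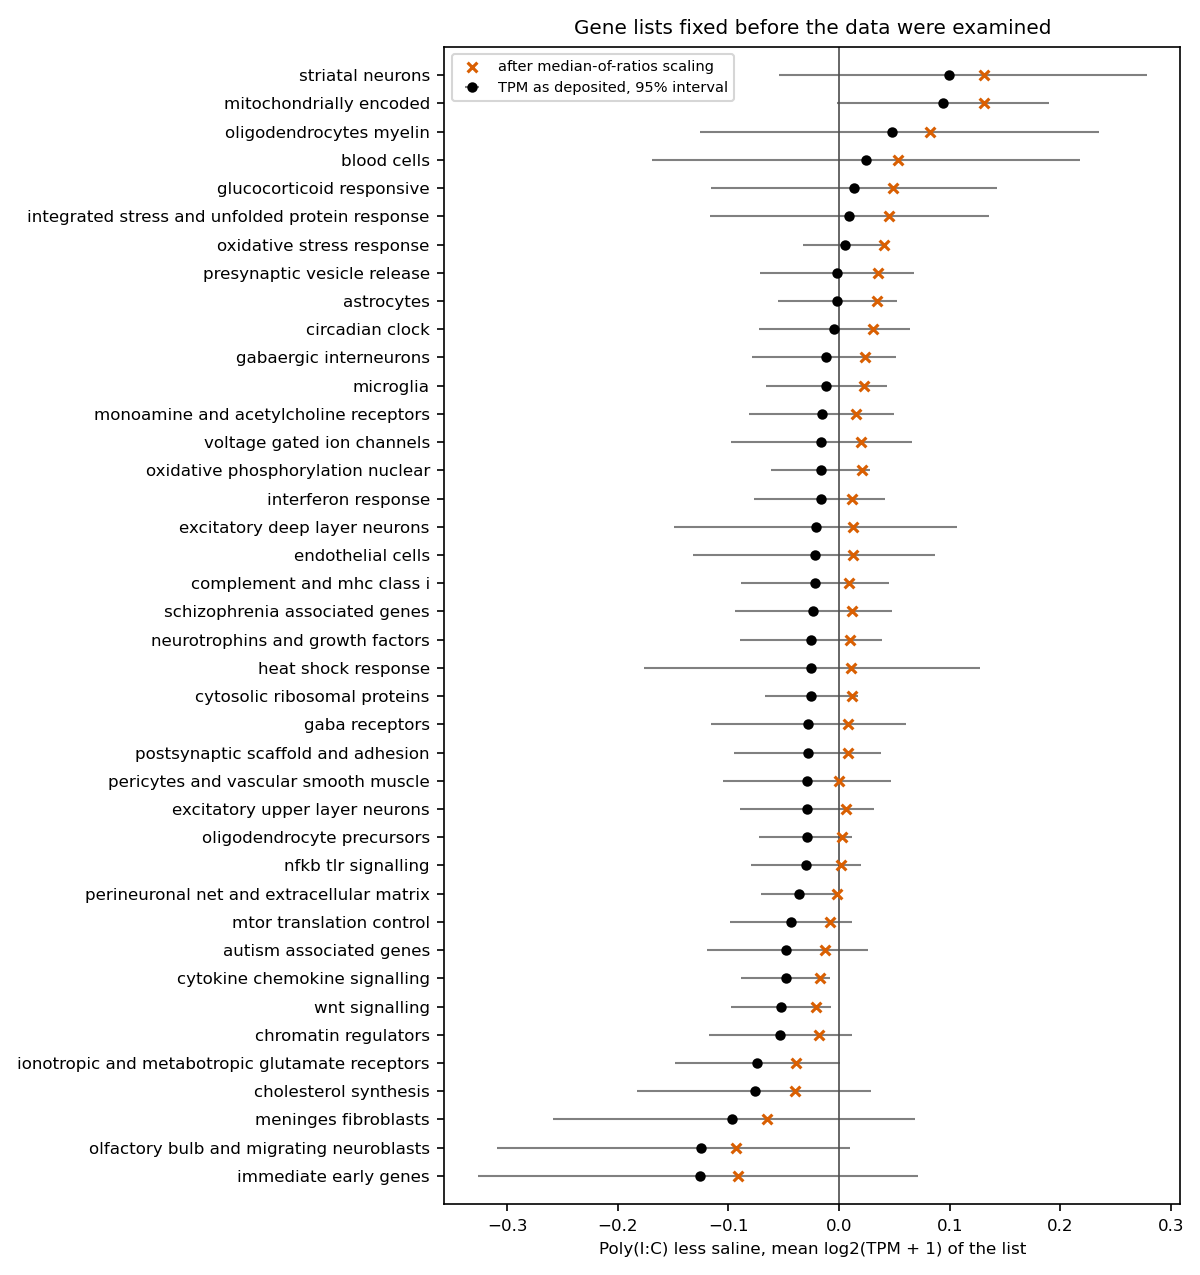
Difference of group means, Poly(I:C) less saline, in mean log2(TPM + 1) for each of 40 gene lists, with black points and 95% intervals for TPM as deposited and orange crosses for values after median-of-ratios scaling. As deposited 33 lists lie below 0 and 7 above, and after median-of-ratios scaling 12 lie below and 28 above. That scaling levels the median gene ratio between libraries, so it moved the lists up together.

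Over the 40 tested lists 0 passed an adjusted p of 0.05 by exact permutation of the list means, and 3 had an unadjusted p under 0.05 as deposited. After median-of-ratios scaling the exact permutation p of these 3, the cytokine, Wnt and perineuronal net lists, were 0.322, 0.275 and 0.914. The 1 list under 0.05 was then oxidative stress, higher by 0.041, with an exact permutation p of 0.0160 and an adjusted p of 0.638. Without replicate 7 of both groups 1 list, perineuronal nets, lay under 0.05, with an exact permutation p of 0.0359 and an adjusted p of 0.918. Leaving out these 2 libraries moved the difference of 21 of the 40 lists by over 1.5 times. No member of any list passed in limma over all genes tested, while 5 lists held members that passed adjusted over the list alone, as given above. That adjustment takes no account of the 40 lists searched, so some such passes can arise by chance. The 95% intervals of the list differences had half-widths between 0.035 and 0.20, with a median of 0.069.

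Neither did the main directions of variation separate the groups. The first principal component held 12.8% of the variance, with mean scores of 3.09 ± 8.07 in the Poly(I:C) group (SD, n = 9) and -3.48 ± 7.14 in the saline group (SD, n = 8) and an exact permutation p of 0.0977. The second component held 10.3% and had an exact permutation p of 0.0993. After adjustment over 5 components the smallest p was 0.248, and 0 of 5 components passed.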

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

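The tests of the 2 libraries that stood apart, of the spread without them, of the copies of Rps27rt, mt-Co2 and Gm21093, and of the other splits of the samples were chosen after the result was seen.

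Among 318 groups of values, 22 held 1 library far from the others, where chance gives about 1 in 20, or 15.9, and 9 of the 22 fell on Poly(I:C) replicate 7 and 4 on saline replicate 7. The gap to the nearest library as a share of the group's range is given for each. In Poly(I:C) replicate 7 it was 0.543 for the myelin list mean, 0.509 for the striatal list mean, 0.627 for Mbp (1966 TPM), 0.632 for Bcas1 (135 TPM), 0.582 for Foxj1 (3.13 TPM) and 0.582 for Rorb (7.63 TPM), all highest. The same library was lowest in Meis2 (0.507, 113 TPM), Cck (0.541, 739.5 TPM) and Scn3a (0.500, 5.51 TPM). Saline replicate 7 was highest in the olfactory list mean (0.782), the interneuron list mean (0.554), Tceal5 (0.566, 205 TPM) and Ndufa1 (0.592, 203 TPM). Other libraries stood apart in the interferon response list mean (Poly(I:C) replicate 6, lowest, 0.514), Mmp16 (Poly(I:C) replicate 4, 0.635), Mef2c (Poly(I:C) replicate 4, 0.638), Parg (Poly(I:C) replicate 3, 0.495), Ndufa1 (Poly(I:C) replicate 8, 0.541) and Fdft1 (Poly(I:C) replicate 5, lowest, 0.519). In the saline group these were Actb (replicate 1, 0.559), Taf1b (replicate 5, 0.532) and Foxj1 (replicate 3, 0.701).

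Tissue from neighbouring regions is a candidate explanation for the 2 libraries that stood apart, and it was set against no biological explanation, since the labels give these animals nothing of their own. Poly(I:C) replicate 7 was the highest of 17 libraries in 13 of 20 striatal list members, where the highest other library led in 2, with Drd2 at 7.57 TPM against a median of 1.27 TPM in the other libraries and Syndig1l at 11.6 against 1.68 TPM. Saline replicate 7 was the highest in 18 of 20 olfactory list members, where the highest other library led in 1, with Cdhr1 at 11.0 against 1.01 TPM and Th at 7.91 against 2.03 TPM. The 2 libraries were picked by the means of the same lists, so the counts show only that most members, and not a few, carried those means, and they are no separate test of the tissue. Striatal or olfactory bulb tissue in the dissection and a difference between animals in these transcripts both stay open, and members such as Foxp1 and Meis2 are also present in the other libraries.

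Poly(I:C) libraries lay further from their group centre, at 23.3 ± 1.26 (SD, n = 9) against 21.7 ± 1.202 (SD, n = 8) in log2 units over all tested genes, with an exact permutation p of 0.0138. The distances were measured from the centres of the real groups, so libraries of a group are not independent. The p-values of the distances are therefore approximate. Counting noise in shallower libraries would weigh on genes of low TPM, yet the ratio of the distances was 1.05 in the lowest tertile of genes by mean TPM (exact p of 0.105), 1.11 in the middle (0.00712) and 1.13 in the highest (0.0478, close to the threshold). The share of a few abundant transcripts and the 2 libraries that stood apart were argued against as the whole cause by exact p of 0.00263 after quantile normalization and 0.00855 without the 2 libraries. Leaving out these 2 cannot speak on uneven dissection among the remaining libraries. With protein-coding genes only, the exact p was 0.0846 and the distances were 18.2 and 16.9. Litters, which the labels do not tie to animals, dissection of the remaining libraries and the prenatal exposure may each underlie the wider spread, and none was tested. The comparison of spread was not part of the fixed design and was not adjusted, so chance stays open too.

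Reads shared with near-identical copies were weighed for 4 leading genes, none past the threshold as deposited. The summed difference was 6.08 TPM for Rps27rt and Rps27 (95% interval -16.0 to 28.1), 765 TPM for mt-Co2 and Gm28661 (-1158 to 2691) and 7.53 TPM for Gm21093 and its 8 copies (-2.03 to 17.1). Each interval holds 0 and the difference of the gene alone, 17.7, 288 and 5.001 TPM, so a shift of reads between copies cannot be told apart from a difference of the gene. Rps27rt held 13.7% of its sum, and Rps27 alone differed by -11.6 TPM, opposite to Rps27rt, with an exact permutation p of 0.293. The copies of mt-Co2 and Gm21093 differed in the direction of the gene, by 477 and 2.53 TPM. For Gm8325, Ube2v1 and Gm20431 the summed difference was -37.1 TPM (-57.8 to -16.2). Ube2v1 alone differed by 7.89 TPM in the other direction, with an exact permutation p of 0.0131. TPM is divided by transcript length, so reads that move between copies of unlike length change the sum. The sum therefore cannot decide on sharing for Gm8325 either. The prenatal exposure stays open for all 4 and was not tested apart from litters.

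With 0 genes past an adjusted p of 0.05 in the real grouping, splits of the 17 samples into 9 and 8 cannot speak on chance, since any split gives at least as many (100 of 100, the real one included; the highest other gave 1). For genes under an unadjusted p of 0.05, where the real grouping gave 1237, chance could not be excluded, as 11 of 100 splits, the real one included, gave as many and the highest other gave 2423. Chance could not be excluded for the lean to lower values either, with a median log2 difference of -0.035, since 1907 of 24310 splits lay as far from 0 and the largest other reached 0.068.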

How the results depend on the processing

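Leaving out Poly(I:C) replicate 7 with saline replicate 7, and rescaling without mitochondrial genes or without the 50 most abundant genes, were chosen after seeing the data. With 0 genes past an adjusted p of 0.05 by limma (1237 under an unadjusted p of 0.05; by the rank test 0 and 1132), 2 genes passed with median-of-ratios scaling (1110008P14Rik and Gm21093), 2 with a replicate block (Gm21093 and Rps27rt), and 0 to 1 when each library was left out in turn, the 1 being Rps27rt without saline replicate 4. The replicate numbers did not pair the samples, as 0 of 8 pairs correlated above 0.1. The block fit also left out Poly(I:C) replicate 9, which has no saline library of its number. Leaving out that library alone gave a smallest adjusted p of 0.0511 in limma. The smallest adjusted p ran from 0.0344 with the replicate block to 0.335 without the 2 libraries. When each library was left out in turn, the count under an unadjusted p of 0.05 ran from 843 without saline replicate 7 to 1710 without saline replicate 6. It was 819 without the 2 libraries, 749 with the first principal component as a covariate and 1763 with no filter, where 26534 genes were tested. For lists, 0 passed by permutation as deposited, with a pseudocount of 0.1, median-of-ratios, quantile, z scores, rescaling without mitochondrial genes, without the 2 libraries and without each library in turn, with a smallest adjusted p of 0.134, and fry gave 0. Upper-quartile scaling, rescaling without the top 50, other filters and covariates were not run for lists. Camera with a preset correlation gave 5 lists (adjusted p 3.44e-07 for mitochondrially encoded and striatal, 0.000216 for myelin, 0.0078 for blood cells and 0.0335 for glutamate receptors), and with the correlation estimated from the data it gave 0, so these calls rest on the preset. No principal component passed in any setting run. Genes lower in the Poly(I:C) group made up 71.0% as deposited, 50.9% with median-of-ratios, 51.9% with upper-quartile, 49.3% with quantile scaling and 57.7% rescaled without mitochondrial genes. The 27 leading genes kept their direction in all 884 recomputed values, which is no separate support, since they were picked by smallest p in the same libraries. Of 3871 recomputed values of named genes 23 changed sign, and of 919 of lists 103, in 28 lists, none of them past an adjusted p of 0.05. TPM keeps no depth, so its effect could not be computed.

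The values that changed sign follow by setting, on the log2 scale; for scaling the lean of all genes moved with them, and otherwise the cause was not tested. Median-of-ratios scaling gave 0.026 for Bsg, 0.017 for Enpp2, 0.016 for Uty, 0.011 for interferon response, 0.0020 for nfkb tlr signalling, 0.0088 for complement and mhc class i, 0.023 for microglia, 0.034 for astrocytes, 0.0028 for oligodendrocyte precursors, 0.013 for endothelial cells, 0.0061 for excitatory upper layer neurons, 0.013 for excitatory deep layer neurons, 0.023 for gabaergic interneurons, 0.0081 for gaba receptors, 0.015 for monoamine and acetylcholine receptors, 0.035 for presynaptic vesicle release, 0.0083 for postsynaptic scaffold and adhesion, 0.0095 for neurotrophins and growth factors, 0.011 for heat shock response, 0.031 for circadian clock, 0.020 for voltage gated ion channels, 0.011 for schizophrenia associated genes, 0.021 for oxidative phosphorylation nuclear, 0.012 for cytosolic ribosomal proteins. Quantile normalization gave 0.0052 for Enpp2, 0.0069 for Kdm5d, 0.023 for Uty, 0.023 for interferon response, 0.0095 for nfkb tlr signalling, 0.019 for complement and mhc class i, 0.027 for microglia, 0.024 for astrocytes, 0.010 for oligodendrocyte precursors, 0.017 for endothelial cells, 0.0089 for pericytes and vascular smooth muscle, 0.0050 for excitatory upper layer neurons, 0.017 for excitatory deep layer neurons, 0.020 for gabaergic interneurons, 0.0037 for gaba receptors, 0.024 for monoamine and acetylcholine receptors, 0.013 for presynaptic vesicle release, 0.0090 for neurotrophins and growth factors, 0.00090 for heat shock response, 0.029 for circadian clock, 4.4e-05 for perineuronal net and extracellular matrix, 0.018 for voltage gated ion channels, 0.0072 for schizophrenia associated genes, 0.0079 for oxidative phosphorylation nuclear. Rescaling without mitochondrial genes and copies gave 0.014 for Bsg, 0.0058 for Enpp2, 0.0073 for Uty, 0.0030 for interferon response, 0.012 for microglia, 0.023 for astrocytes, 0.0013 for endothelial cells, 0.0019 for excitatory deep layer neurons, 0.012 for gabaergic interneurons, 0.0063 for monoamine and acetylcholine receptors, 0.024 for presynaptic vesicle release, 0.021 for circadian clock, 0.0083 for voltage gated ion channels, 0.0017 for schizophrenia associated genes, 0.0092 for oxidative phosphorylation nuclear, 3.7e-05 for cytosolic ribosomal proteins. Upper-quartile scaling gave 0.024 for Bsg, 0.016 for Enpp2, 0.015 for Uty. Rescaling without the top 50 gave 0.014 for Bsg, 0.0053 for Enpp2, 0.0069 for Uty. Leaving out the 2 libraries set apart gave -0.0014 for Bcas1, 0.0011 for Bsg, 0.0018 for microglia, -0.012 for oligodendrocytes myelin, 0.011 for gabaergic interneurons, 0.0060 for presynaptic vesicle release, -0.012 for glucocorticoid responsive. The striatal list as a covariate gave -0.0079 for Bcas1, the first principal component as a covariate -0.0050 for Cck, 0.0021 for Ddx3y, a pseudocount of 0.1 -0.062 for blood cells, and the mean of z scores 0.0049 for astrocytes, -0.0084 for integrated stress and unfolded protein response. Leaving out each library in turn gave ranges of -0.067 to 7.5e-05 for Kdm5d, -0.038 to 0.012 for Uty, -0.016 to 0.011 for astrocytes, -0.018 to 0.011 for presynaptic vesicle release, -0.023 to 0.0071 for circadian clock, -0.040 to 0.00088 for voltage gated ion channels, -0.019 to 0.036 for integrated stress and unfolded protein response, -0.017 to 0.058 for blood cells, -0.013 to 0.046 for glucocorticoid responsive, -0.047 to 0.0060 for excitatory deep layer neurons, -0.026 to 0.011 for gabaergic interneurons, -0.024 to 0.0017 for interferon response, -0.041 to 0.0075 for endothelial cells, -0.017 to 0.088 for oligodendrocytes myelin, -0.061 to 0.0060 for heat shock response, -0.0052 to 0.011 for oxidative stress response.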

Other observations

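The tests of X-linked genes were chosen after Naa10 and Tceal5 had been seen among the leading genes. A candidate explanation for their lower values was a difference of the X chromosome as a whole. The mean of 435 X-linked protein-coding genes, relative to all protein-coding genes, differed by -0.013 on the log2 scale (95% interval -0.028 to 0.0024), with an exact permutation p of 0.0932 and an adjusted p of 0.622 over 21 chromosomes. The plain mean log2(TPM + 1) of X-linked genes in each library, not set relative to all genes, was also subtracted. It includes the lean of all genes to lower values. Less this mean, Naa10 differed by -0.13 (-0.19 to -0.070) and Tceal5 by -0.22 (-0.34 to -0.092), and the X-linked leading gene Apool by 0.28 (0.14 to 0.43) in the other direction. Naa10, Tceal5 and Apool were picked for their small p in these libraries, so intervals off 0 follow largely from that choice. They do not decide whether a shift of the whole chromosome had a part in these values, and a small shift of X-linked genes stays undecided.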
